A study of Arabidopsis thaliana with 10 samples.

How the data were processed

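The deposited data were 10 tables of a 1-colour microarray, each from 1 hybridization of labelled RNA from whole Arabidopsis seedlings, and 1 value table of the whole series. The authors extracted the arrays with Agilent Feature Extraction 10.7.1.1. Per the file headers, the processed signal of each spot is an intensity on a linear scale, background-subtracted and detrended within the array, with no normalization between arrays. The median spot signal and the median local background are intensities too, and were used for 1 alternative. The deposited value table also holds an intensity. Its column medians ran from 966.71 to 970.13, and its columns shared their lowest and highest values, as after quantile normalization. The files do not state that step, so its exact scale and settings are unknown; the value table was used only as an alternative to the processed signal.

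Each array held 45220 spots, of which 43803 were no controls and carried 43603 probes. Gene names came from a reference table of assembly TAIR10.1, which was used only for names and for the order of genes along chromosomes. Accessions in the array tables gave a locus for 34358 probes, and 9245 probes stayed without a locus and were left out of the gene counts. The 34358 probes stood for 25433 loci. Spots that the software marked as outliers were left out, and no spot was saturated. Signals were divided by their array's 75th percentile and put on a log2 scale. A probe was kept if it was well above background, by the software's own flag, on at least 1 array. Each gene was represented by its probe with the highest mean over the 10 arrays, so a gene's value rests on 1 probe. This left 22355 genes. Division by 1 number per array leaves differences in the shape of the intensity distribution between arrays, and the low end of the scale holds values that the software replaced by surrogates. Fold changes of dim genes therefore depend on background. Where a gene was well above background on no array of 1 group, its fold change is given as a lower bound ("at least"), computed with each array's lowest well-above-background signal as the floor, while its log2 change is the fitted one and is not a bound. Where at least 1 array of each group was well above background, the fitted fold is given, even if other arrays lay at background.

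Genes were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes variances and Benjamini-Hochberg adjustment over the 22355 genes, at an adjusted p under 0.05. Changes over both ages came from a fit of genotype and age to all 10 arrays, in which the 2 ages of a mutant served as its samples (5 residual degrees of freedom). Changes at 1 age came from a fit of the 8 group means, whose spread comes from the WT pairs alone (2 residual degrees of freedom), so each lone mutant array was assumed to vary like the WT arrays. WT at 15 days was compared with WT at 7 days on the 4 WT arrays. The 2 WT arrays of an age lay on different slides, so the spread in both of these fits includes any difference between slides. All p-values measure only the spread between these arrays, which may be technical as well as biological. These tests, the gene lists and the rule for naming genes were chosen before the data were examined. The arrays lay on 3 slides, as the scan barcodes in the files show, and each comparison was repeated with slide as a further term. The other alternatives fixed in advance were quantile normalization, the authors' value table, a stricter filter (5 arrays) or none, a floor under dim signals, the mean of a gene's probes, a 2-fold threshold, an intensity trend with robust variances, the 8 group means, and leaving out each array. A background correction by normexp on mean signals was planned and could not be run, since the deposited tables lack that column; median signals with an offset of 50 were used instead. That repeat, a block of slide 1 against slides 2 and 3, fits within slides and the inclusion of probes without a locus were chosen after seeing the data.

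Lists of genes of known function were tested with camera from limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 19 lists within a comparison. The lists covered floral organ identity, flowering time, the Polycomb and trithorax group, seed maturation, shoot meristem and KNOX genes, stamen and pollen, carpel and ovule, cold, drought and abscisic acid, salicylic acid defence, jasmonate and ethylene defence, anthocyanin and flavonoid synthesis, aliphatic glucosinolate synthesis, photosynthesis, the circadian clock, heat shock, auxin, root tissue, the cell cycle and leaf senescence. Of 350 entries, 10 were dropped because the symbol was not among the names of the locus, and 323 of the remaining 340 passed the filter. Of 114 tests of lists, 28 had an adjusted p under 0.05 with the preset correlation and 3 with the estimated correlation. The lists of anthocyanin and flavonoid synthesis, of the carpel and ovule, of the circadian clock and of stamen and pollen passed in no comparison without slide as a term (smallest adjusted p 0.167, 0.131, 0.178 and 0.0762); with slide as a term the circadian clock list passed in 3. The other lists are described with the comparisons in which they passed.

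The genes named for a comparison over both ages were the 10 with the largest increase and the 10 with the largest decrease among those that passed the test, changed in the same direction at both ages and had a gene symbol. For a comparison at 1 age the rule was the 5 largest each way among those that passed, and where none passed, the 5 largest each way without a call. At 1 age it was applied only to genes with a symbol, a limit that the rule fixed in advance did not hold, so larger changes of loci without a symbol are mostly not named. EMF1, ULT1 and LFY were always looked at, as were the called members of each list and up to 4 members with the largest differences. Loci without a symbol that are named were chosen after their values were seen.

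In a self-test, changes of known size were added to 40 genes per size in simulated data of 22355 genes. For LFYasEMF1 against WT over both ages, limma recovered 10% of genes changed by a log2 of 1, 60% at 2, 77.5% at 3, 92.5% at 4 and 100% at 6, with 6 false calls among 142. For LFYasEMF1 against WT at 7 days it recovered 0%, 0%, 12.5%, 60% and 85% at the same sizes, and for WT at 15 against 7 days 0%, 2.5%, 52.5%, 77.5% and 95%. Camera called 0 of 18 lists drawn at random. A set ratio of 0.4 between the changes in the double mutant and in LFYasEMF1 was found as 0.391. The simulated genes varied independently of each other, and no difference between slides was added. The self-test therefore cannot show how the calls, camera or the ratio behave where genes are correlated or slides differ.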

Results

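Gene expression was measured in whole seedlings of Arabidopsis thaliana of 4 genotypes, raised on agar in short days and harvested at 7 or 15 days of age. EMF1 is a protein of the Polycomb system that keeps flower genes silent in seedlings, and LFYasEMF1 is a line that expresses antisense EMF1 RNA from the promoter of LEAFY (LFY). ULT1 is a SAND-domain protein of the trithorax group, known as an activator of the floral gene AG, and ult1-3 is a mutant allele of it. LFYasEMF1/ult1-3 combines both and is called the double mutant. Wild type (WT) had 2 arrays per age, and each mutant had 1 array per age, 10 arrays in 8 groups. By the title of the series, the purpose was to learn whether ult1-3 restores what LFYasEMF1 alters, here at the level of transcripts.

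Between 71.7% and 80.1% of the spots were well above background on each array (31418 to 35097 spots), and the 75th percentile of signal ran from 3723 to 5996. The number of arrays limits the precision of every value. The WT arrays of an age differed between themselves by a median absolute log2 of 0.57 at 7 days and 0.57 at 15 days, and by more than 2-fold in 5931 and 5478 of 22355 genes. The first 2 principal components held 28.5% and 25.5% of the variance.

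The arrays lay on 3 slides. Slide 1 held replicate 1 of WT at both ages and both LFYasEMF1 arrays, slide 2 held WT replicate 2, ult1-3 and the double mutant at 7 days, and slide 3 held the same at 15 days. Transcripts of the circadian clock followed this layout in WT. The morning gene LHY was lower on slide 1 than on the other slide by a log2 of 9.17 at 7 days and 5.39 at 15 days, and the evening gene ELF4 was higher by 4.93 and 7.22. Over 6 evening and 6 morning genes, the median evening minus morning signal on an array lay between 1.83 and 5.14 on slide 1 and between −4.32 and −3.69 on slides 2 and 3. LFYasEMF1 therefore lay with WT replicate 1 on one side of this difference, and ult1-3 and the double mutant lay with WT replicate 2 on the other. The small heat shock protein genes HSP17.6II, HSP17.6A and HSP17.4 split in the same way, with HSP17.6II at −7.42 and −7.10 (log2 of the scaled signal) in WT on slide 1 and at 0.42 and −1.99 in WT on slides 2 and 3. HSP18.2, of the same family, did not (−4.61 and −3.67 against −3.72 and −3.94).

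**Figure D1:**
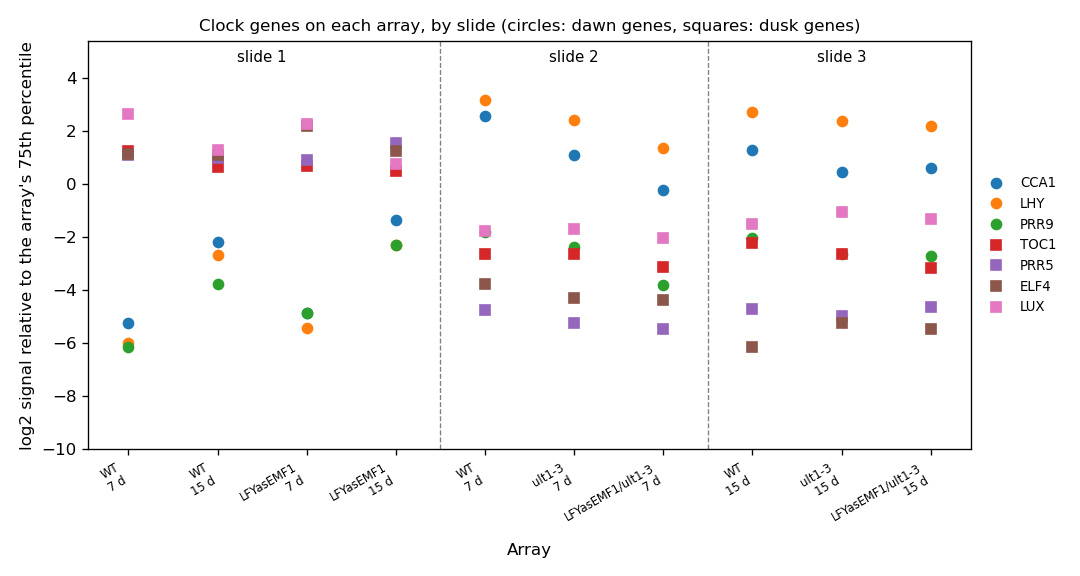
Log2 signal relative to the array's 75th percentile of morning genes (CCA1, LHY and PRR9, circles) and evening genes (TOC1, PRR5, ELF4 and LUX, squares) on each of the 10 arrays, grouped by slide. On the 4 arrays of slide 1 the evening genes sit above the morning genes, and on the 6 arrays of slides 2 and 3 they sit below CCA1 and LHY, while PRR9 lies among them.

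The transcripts of the altered genes were examined first. ULT1 had a log2 change of −2.06 ± 0.35 (SE, 2 arrays against 4) in ult1-3 and fell by 5.65 ± 0.35 in the double mutant, and 2 probes gave −2.06 and −1.99 in the former and −5.65 and −5.38 in the latter. Where these probes lie relative to the ult1-3 lesion is not given, so the values do not tell how much functional transcript is lost. In ult1-3 the change of ULT1 was 4.17-fold and did not pass the limma test over all genes (adjusted p = 0.3), whereas in the double mutant it was 50.1-fold (adjusted p = 0.000274). Between the double mutant and ult1-3, ULT1 fell by a further 3.59 ± 0.41, or 12-fold (adjusted p = 0.0125 by limma), a call that ended without either ult1-3 array or the double mutant array at 7 days (adjusted p = 0.149, 0.104 and 0.111). The EMF1 probe differed from WT by 0.83 ± 0.36 in LFYasEMF1, −0.21 ± 0.36 in ult1-3 and −0.43 ± 0.36 in the double mutant, none of which passed (adjusted p = 0.426, 0.949 and 0.572). The array does not tell whether that probe reads the sense or the antisense transcript of the transgene. The LFY probe was well above background on 2 of the 4 WT arrays and on none of the mutant arrays, so no fold is given.

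LFYasEMF1 was compared with WT to ask what the antisense transgene changes. Genes of floral organ identity rose in LFYasEMF1 seedlings at both ages. SEP2 (AT3G02310), a MADS-box cofactor of all floral organ identities, rose by a log2 of 8.75 ± 0.45 (430-fold, 2 arrays against 4), and SEP1 (AT5G15800) rose by 8.02 ± 0.87 (260-fold). SEP2 and SEP1 were well above background on 1 and 2 of the 4 WT arrays, so these folds rest in part on background. AP3 and PI, which specify petals and stamens, rose at least 169-fold and 34.6-fold (8.50 ± 0.69 and 5.11 ± 0.36). AP1, a meristem and sepal identity gene, rose at least 135-fold (8.27 ± 0.76), and AG, which specifies stamens and carpels, rose 62.4-fold (5.96 ± 0.51), with a second AG probe at 4.1. The ovule gene STK rose at least 87.5-fold, and the carpel genes SHP1 and SHP2 rose 19.4-fold and 35.8-fold (4.27 ± 0.60 and 5.16 ± 0.49). Of the 18 genes tested on this list, 12 rose (adjusted p from 7.92e-05 to 0.0137 by limma), the others of them being CAL, SEP3 and SUP, and 15 were higher and 1 lower when adjusted over the list alone. The list's median log2 change was 4.31, also with dim genes at their bound, and 4.13 against WT of the same slide, where 16 of 18 genes were higher. It passed with the preset correlation (adjusted p = 1.08e-22) and with an estimated correlation (adjusted p = 0.0291), though not when slide was a term and the correlation was estimated (adjusted p = 0.334). The calls of 3 members rested on single arrays. Without the LFYasEMF1 array at 7 days the adjusted p was 0.102 for SEP3 and 0.13 for SHP1, without that at 15 days it was 0.0525 for SEP1 and 0.0523 for SEP3, and with slide as a term it was 0.0566 for SEP3.

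**Figure D2:**
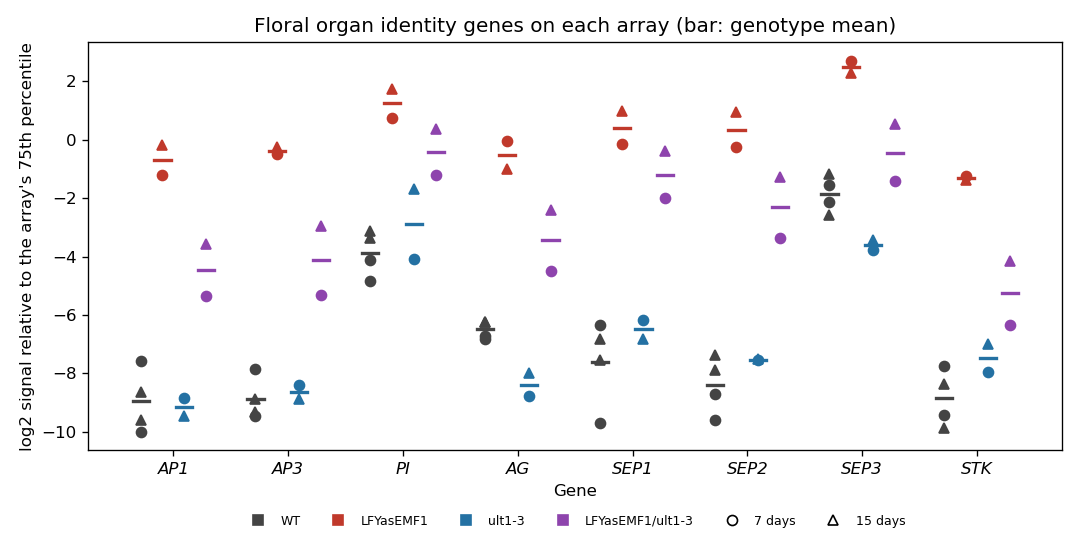
Log2 signal relative to the array's 75th percentile of floral organ identity genes on each of the 10 arrays, by genotype (colour) and age (circles 7 days, triangles 15 days), with bars at genotype means. SEP2 sits at a mean of −8.40 on the 4 WT arrays, 0.35 on the 2 LFYasEMF1 arrays and −2.31 on the 2 double mutant arrays.

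Other genes with large increases in LFYasEMF1 were MEO (at least 38.8-fold), the MADS-box gene AGL71 (at least 17.5-fold), the copper transporter gene COPT3 (at least 15.1-fold) and the sugar transporter gene SWEET10 (127-fold, 6.99 ± 1.24). SWEET10 had an adjusted p of 0.0372 by limma that reached 0.285 without the LFYasEMF1 array at 7 days. Large decreases included those of the phloem lectin genes PP2-A8 and PP2-A6 (at least 34.0-fold and 16.8-fold), ACS4, an enzyme of ethylene synthesis (at least 9.65-fold), and LBD26 (at least 5.34-fold). ACS4 missed the threshold without the LFYasEMF1 array at 15 days (adjusted p = 0.0523). LOH1 (AT3G25440) fell at least 37.8-fold by the probe chosen, while its other probe gave a change of 0.47, so the probes of this gene disagree. The genes named here as lower are all among the 66 genes at background in LFYasEMF1. Whether these reflect differences between the lines is weighed below.

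Auxin genes fell as a list in LFYasEMF1 (median −0.84, 14 of 15 lower, adjusted p = 5.59e-06, and adjusted p = 0.0295 with an estimated correlation), and their median was −0.88 against WT of the same slide. With slide as a term the estimated correlation gave an adjusted p of 0.24. The auxin-responsive gene IAA29 fell by 1.49 ± 0.23 and the auxin synthesis gene YUC2 by 1.72 ± 0.30 (adjusted p = 0.023 and 0.0327 by limma), and 6 members were lower when adjusted over the list alone. Both calls ended without single arrays, with adjusted p up to 0.253 for IAA29 (without LFYasEMF1 at 15 days) and 0.252 for YUC2 (without LFYasEMF1 at 7 days). The flowering time list rose (median 0.41, adjusted p = 0.00811, and adjusted p = 0.45 with an estimated correlation). Its called member was TFL1, a repressor of floral fate, at 2.16 ± 0.38 (adjusted p = 0.0359, and 0.0957 with slide as a term), while the repressor FLC stood at 2.39 ± 0.47 (adjusted p = 0.0579). The leaf senescence list rose (median 0.76, adjusted p = 0.0177, and adjusted p = 0.45 with an estimated correlation). Without the LFYasEMF1 array at 15 days neither of these lists passed (adjusted p = 0.113 and 0.474), nor did they with slide as a term (adjusted p = 0.0569 and 0.0532). The heat shock list fell (median −2.39, adjusted p = 0.000511, and adjusted p = 0.469 with an estimated correlation), but against WT of the same slide its median was −0.11 with 5 of 10 genes lower, and HSP17.6II, HSP17.6A and HSP17.4 split between slides in WT. Its member HSP18.2 fell by 2.95 ± 0.31 (adjusted p = 0.00271; 0.0529 without LFYasEMF1 at 15 days).

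In all, 207 genes rose and 168 fell in LFYasEMF1 over both ages (limma, adjusted p under 0.05), each by at least 2-fold in the fit. With slide as a term 485 genes passed, 301 of the 375 among them, and against WT on slide 1 alone 302 passed, 222 among them. The fit of the 8 group means gave 155 genes, 87 up and 68 down, with 144 of the 375 among them, and a filter of 5 arrays gave 126 up and 170 down. The count was 239 and 181 without the LFYasEMF1 array at 7 or at 15 days, 249 without either ult1-3 array and 563 without WT replicate 1 at 15 days.

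The comparison of ult1-3 with WT asked what the ult1-3 allele alone changes in seedlings. Few genes passed, 11 up and 3 down over both ages. MRD1 fell by 5.45 ± 0.26 (43.8-fold, adjusted p = 0.00051 by limma, 2 arrays against 4), and ARI3, a gene of the ARIADNE family of ubiquitin ligases, rose by 3.98 ± 0.31 (15.8-fold, adjusted p = 0.00422). ARI3 was well above background on 1 of the 4 WT arrays, so its fold rests in part on background. LCR80, a gene for a small cysteine-rich protein, rose at least 2.18-fold (adjusted p = 0.00615, and 0.0658 with slide as a term). Chosen after their values were seen, AT2G45135 rose 49.0-fold and AT2G25330 at least 15.6-fold, and AT5G01080 fell at least 9.88-fold. AT5G01080 is also the 1 gene of the 82 described below that was called lower and lay at background in ult1-3. In LFYasEMF1 and the double mutant its other probe gave −1.85 and −0.32, while the probe chosen lay at background, so its probes disagree. Without the ult1-3 array at 7 or 15 days ARI3 had an adjusted p of 0.0586 or 0.0851, LCR80 of 0.0939 or 0.138 and AT5G01080 of 0.0506 or 0.0851.

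The floral organ identity list did not pass in ult1-3 (adjusted p = 0.844, and adjusted p = 0.919 with an estimated correlation), with 9 genes higher and 9 lower and a median of 0.02 (0.52 with dim genes at their bound). Its members went both ways. AG stood at −1.89 ± 0.51, at least 1.37-fold lower, and SEP3 at −1.74 ± 0.56, 3.35-fold lower, and neither passed over all genes (adjusted p = 0.882 and 0.933 by limma) or over the list alone (adjusted p = 0.116 and 0.139). Both ult1-3 arrays lay below all 4 WT arrays for AG (−8.78 and −7.99 against −6.81 to −6.23) and for SEP3 (−3.78 and −3.42 against −2.58 to −1.17). The AG probe was well above background on 0 of the 2 ult1-3 arrays, and the other AG probe gave −1.04, with 1 of the 2 arrays within the range of WT. The flowering time list fell (median −0.69, and −0.45 with dim genes at their bound, adjusted p = 0.0176, and adjusted p = 0.744 with an estimated correlation). It did not pass without WT replicate 2 at 7 days, WT replicate 1 at 15 days or ult1-3 at 15 days (adjusted p = 0.158, 0.0563 and 0.106). None of its 24 members passed singly. The count of changed genes was 14 (966 at an unadjusted p under 0.05), 8 with slide as a term, 5 within slides 2 and 3 and 5 in the fit of the 8 group means, all of which were among the 14. It was 5 without the ult1-3 array at 15 days.

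In the double mutant compared with WT, floral organ identity genes rose again. SEP1 rose by 6.42 ± 0.87 (85.4-fold) and SEP2 by 6.09 ± 0.45 (67.9-fold), with only 2 and 1 of the 4 WT arrays well above background. PI rose by 3.45 ± 0.36 (10.9-fold), AP3 at least 12.4-fold, AP1 at least 9.89-fold and AG 8.26-fold (3.05 ± 0.51, 2 arrays against 4, and 0.82 by its other probe). These 6 of 18 list members passed the limma test (adjusted p = 0.0165, 0.000709, 0.00471, 0.0227, 0.0495 and 0.0486), and 14 were higher when adjusted over the list alone. When slide was a term 4 members passed, SEP1, SEP2, PI and STK, while AP3, AP1 and AG did not (adjusted p = 0.0675, 0.0618 and 0.0556). The list's median was 2.00, or 1.83 with dim genes at their bound, with 17 of 18 genes higher. Against WT of the same slides it was 1.75, again with 17 of 18 higher. It passed with the preset correlation (adjusted p = 2.96e-12) but not with an estimated correlation (adjusted p = 0.114). SEP2 kept its call in every fit that left out 1 array. SEP1, PI, AP3, AP1 and AG did not, with adjusted p up to 0.103 for SEP1 and 0.0563 for PI without the double mutant array at 7 days, 0.0765 for AP3 without WT replicate 2 at 15 days, and 0.165 and 0.138 for AP1 and AG without the double mutant array at 15 days.

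Genes outside the floral list also changed in the double mutant. The acyl carrier protein gene ACP5 rose 26.2-fold (4.71 ± 0.47), ARI3 17.1-fold (4.1 ± 0.31, with 1 of 4 WT arrays well above background) and the MADS-box gene AGL98 at least 6.7-fold. MRD1 fell 71.3-fold (−6.16 ± 0.26) and PP2-A8 at least 27.5-fold, and the neighbouring resistance genes CSA1 and DAR4 fell at least 29.5-fold and 67.2-fold (DAR4 −6.07 ± 0.54, and −5.04 by its other probe). DAR4 was well above background on 1 of the 2 double mutant arrays. PP2-A8 and CSA1 are among the 82 genes at background described below. Enzymes of aliphatic glucosinolate synthesis, the defence compounds of the cabbage family, fell as a list, with all 13 tested genes lower (median −0.97, and −1.23 against WT of the same slides; adjusted p = 0.000697, and adjusted p = 0.712 with an estimated correlation). No member passed singly, and 3 were lower when adjusted over the list alone. The regulator MYB28 stood at −1.92 ± 0.51, MAM1 at −2.51 ± 0.68 and CYP79F1 at −3.12 ± 1.22 (adjusted p = 0.175, 0.18 and 0.282 by limma). The list's median was −1.63 at 7 days and −0.29 at 15 days, and without the double mutant array at 7 days the list did not pass (adjusted p = 0.257).

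Over both ages 76 genes rose and 105 fell in the double mutant against WT (limma). With slide as a term 327 passed, with 155 of the 181 among them, and within slides 2 and 3 123 passed, with 97 among them. The fit of the 8 group means gave 33 up and 35 down, with 65 of the 181 among the 68. Without the double mutant array at 7 days 120 passed, 73 up and 47 down, so the excess of decreases rests on that array. Of the genes called in LFYasEMF1, 39 were called up and 66 down in the double mutant too, and 1 was called the opposite way. If the calls were independent, 0.7 and 0.79 shared genes would be met. Both comparisons use the same WT arrays, and with LFYasEMF1 set against WT of slide 1 and the double mutant against WT of slides 2 and 3, 22 and 42 genes were shared. Of the 66 decreases shared in the main fit, 30 are genes at background in both lines, described below. That part of the overlap may come from differences between the lines and WT.

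The double mutant was compared with LFYasEMF1 to ask what ult1-3 changes in the presence of the transgene. This comparison lies across the difference in clock transcripts between slide 1 and slides 2 and 3. The floral organ identity list fell, by a median log2 of −2.59, or −2.13 with dim genes at their bound, with 16 of 18 genes lower (adjusted p = 2.31e-06, and adjusted p = 0.21 with an estimated correlation). With slide as a term the median was −2.49 (adjusted p = 0.000883 by camera, and adjusted p = 0.803 with an estimated correlation), and no member passed singly. SUP, which bounds stamens from carpels, fell at least 1.53-fold (adjusted p = 0.0221 by limma), and 11 members were lower when adjusted over the list alone. STK, AP1 and AP3 stood at −3.94, −3.77 and −3.76 and did not pass over all genes (adjusted p = 0.0833, 0.0957 and 0.0782). The call of SUP ended with slide as a term (adjusted p = 0.0965) and without any 1 of the LFYasEMF1 or double mutant arrays (adjusted p from 0.0737 to 0.144).

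Auxin genes rose as a list in the double mutant relative to LFYasEMF1 (median 1.14, 12 of 15 higher, adjusted p = 5.14e-05, and adjusted p = 0.0883 with an estimated correlation). IAA29 rose by 1.78 ± 0.27 (2 arrays against 2, adjusted p = 0.032 by limma, and 0.0788 with slide as a term). The flowering time list fell (median −0.97, 21 of 24 lower, adjusted p = 0.000131, and adjusted p = 0.408 with an estimated correlation). Its called member was SPL3, a promoter of flowering, at −3.35 ± 0.37 (10.2-fold, adjusted p = 0.0105, and 0.0574 with slide as a term). The heat shock list rose (median 2.68, or 2.58 with dim genes at their bound, adjusted p = 0.00264, and adjusted p = 0.673 with an estimated correlation), but with slide as a term its median was −0.60 and its direction was down (adjusted p = 0.2). PRR7, a clock gene, fell by 2.56 ± 0.37 (adjusted p = 0.0298, and 0.102 with slide as a term), alongside the clock difference between the slides. The circadian clock list did not pass in any comparison without slide as a term, but with it the list fell in the double mutant against WT, LFYasEMF1 and ult1-3 (medians −0.52, −0.81 and −0.29, adjusted p = 0.00804, 0.00787 and 0.00344, and adjusted p = 0.733, 0.803 and 0.773 with an estimated correlation).

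Among single genes, MRD1 (91.0-fold, −6.51 ± 0.30), ULT1 (48.8-fold), CSA1 (at least 20.2-fold), DAR4 (35.3-fold, −3.47 by its other probe) and the translation factor gene TIF3C2 (42.0-fold) fell and also passed with slide as a term. By the probes chosen, ULT1, DAR4 and TIF3C2 were well above background on 1 of the 2 double mutant arrays. ACC2 fell 26.1-fold by the probe chosen and stood at −0.58 by another, which was well above background on 1 array. ARI3 rose at least 12.8-fold, LBD26 at least 5.41-fold and LOH1 at least 20.5-fold with slide as a term or without it, though the other LOH1 probe gave −2.50. CSA1, LBD26 and LOH1 are among the 82 genes at background described below, so their changes cannot be assigned to ult1-3. The iron transporter gene IRT1 rose 20.5-fold and the oleosin gene OLEO4 36.5-fold (adjusted p = 0.0385 and 0.0434), and neither passed with slide as a term (adjusted p = 0.126 and 0.14). In all, 82 genes rose and 119 fell (limma), but with slide as a term 67 passed (37 up and 30 down), of which 46 were among the 201, and in the fit of the 8 group means 24 passed (15 up and 9 down), of which 23 were. The count was 45, 51 and 53 without LFYasEMF1 at 7 days, LFYasEMF1 at 15 days or the double mutant at 7 days, and 81 without either ult1-3 array.

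The double mutant was also compared with ult1-3, to ask what the transgene changes in the mutant background. Both genotypes lay on the same slides. The lines may differ in more than the transgene, as weighed below for genes at background. SEP2 rose at least 24.8-fold and AG at least 11.3-fold (4.94 ± 0.59, 2 arrays against 2, and 1.86 by its other probe), with adjusted p of 0.00641 and 0.016 by limma. SEP1 and AP1 stood at 5.31 and 4.70 without passing (adjusted p = 0.141 and 0.138). The floral organ identity list rose (median 2.16, or 1.66 with dim genes at their bound, 16 of 18 higher, adjusted p = 1.5e-24, and adjusted p = 0.0242 with an estimated correlation, but 0.565 with slide as a term and an estimated correlation), and 10 members were higher when adjusted over the list alone. Glucosinolate genes fell as a list (median −0.99, all 13 lower, adjusted p = 8.08e-07, and adjusted p = 0.693 with an estimated correlation), a call lost without the double mutant array at 7 days (adjusted p = 0.22). ESM1, which acts in the breakdown of glucosinolates, fell 11-fold (−3.46 ± 0.45, adjusted p = 0.0234), with an adjusted p of 0.26 without ult1-3 at 15 days. The jasmonate and ethylene defence list rose (median 0.63, 17 of 22 higher, adjusted p = 0.000597, and adjusted p = 0.693 with an estimated correlation). It did not pass without the 15-day array of ult1-3 or of the double mutant (adjusted p = 0.545 and 0.329), and its member with the largest difference, THI2.1, stood at 4.16 (adjusted p = 0.55).

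In this comparison 34 genes rose and 52 fell (limma). With slide as a term 97 passed, with 72 of the 86 among them, and within slides 2 and 3 69 passed, with 53 among them. In the fit of the 8 group means 24 passed (6 up and 18 down), all among the 86. The count was 38 and 23 without ult1-3 at 7 or 15 days and 48 and 53 without the double mutant at 7 or 15 days. PP2-A8 (at least 37.4-fold), CSA1 (at least 25.3-fold), WOX2 (at least 14.7-fold), PP2-A6 (at least 11.8-fold) and CYP712A2 (at least 5.1-fold) fell. All of these are among the 82 genes at background described below, so their decreases cannot be assigned to the transgene. Without single arrays WOX2 had an adjusted p up to 0.244 (ult1-3 at 7 days) and PP2-A6 up to 0.105 (ult1-3 at 15 days).

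**Figure D3:**
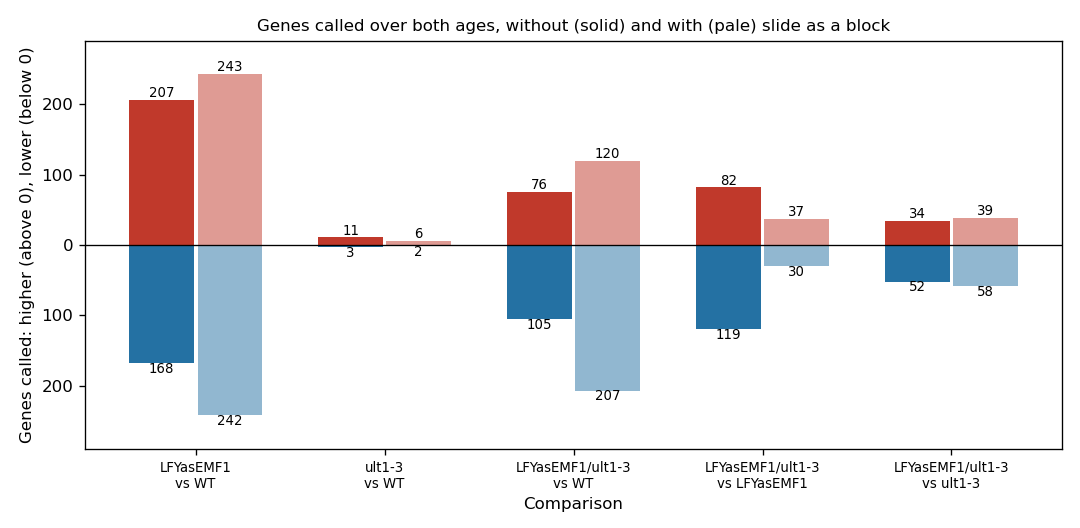
Number of genes with an adjusted p under 0.05 by limma in each comparison over both ages, with increases above 0 and decreases below, without (solid) and with (pale) slide as a term. LFYasEMF1 against WT had 375 genes, the double mutant against WT 181 and ult1-3 against WT 14 without that term.

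To ask how far the double mutant lay from WT at the genes that LFYasEMF1 altered, genes were selected at 1 age and measured at the other. The 200 genes selected at 7 days changed in LFYasEMF1 at 15 days by a median log2 of 3.69 in the direction of selection, in the double mutant by 1.23 and in ult1-3 by 0.20. The double mutant kept 33.4% of the LFYasEMF1 change, was closer to WT at 146 of the 200 genes and moved in the same direction as the selection at 176. For 200 genes selected at 15 days and measured at 7 days, the medians were 3.56, 1.26 and 0.50, the share was 35.5%, and 140 genes were closer to WT. The differences between the medians of the double mutant and LFYasEMF1 were −2.46 and −2.29. With each mutant set against WT of its own slide, 124 and 131 of the 200 genes were closer to WT. The medians in LFYasEMF1 and the double mutant were then 3.56 and 1.50 at 15 days and 3.75 and 1.32 at 7 days. The differences between the medians were −2.06 and −2.43. They were −4.47 and −3.78 for 50 genes selected, −1.61 and −1.21 for 500, −1.63 and −1.47 with normexp on median signals, −2.02 and −1.93 with a filter of 5 arrays and −2.92 and −2.62 with slide as a term. With dim genes at their bound the medians were 3.19 and 0.82 at 15 days and 3.15 and 0.90 at 7 days. No p-value is given, since genes are not replicates. The 82 genes at background described below were not left out of these selections. Differences between the lines at such genes may therefore enter the share kept and the number closer to WT. The 66 of them at background in LFYasEMF1 are all among the 375 genes called there. Over the 375 genes called in LFYasEMF1, a set chosen on the same arrays, the median was 3.02 in LFYasEMF1 and 0.94 in the double mutant (2.37 and 0.79 with dim genes at their bound), and 112 of them were called the opposite way between the double mutant and LFYasEMF1. Of all 201 calls of that comparison, between 140 and 197 passed with other normalizations, filters, probe summaries or variances. Without LFYasEMF1 at 7 days, LFYasEMF1 at 15 days or the double mutant at 7 days 39, 38 and 40 passed, and between 79 and 182 without any 1 of the remaining arrays. The number was 46 with slide as a term, 44 with a block of slide 1 against slides 2 and 3, and 23 in the fit of the 8 group means.

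At single ages the mutants had no replicates, and the test rests on the spread of the WT pairs. The 2 WT arrays of each age lay on opposite sides of the clock difference between slides. That spread therefore includes the slide difference, while each mutant lay on 1 side only. With slide as a term, the fits at single ages had infinite prior degrees of freedom, so all genes shared 1 variance. Larger counts with that term can therefore not be read as a gain from it. In LFYasEMF1 at 7 days SEP2 (at least 160-fold), AP3 (at least 136-fold), AG (104-fold) and TIF3C2 (at least 41.3-fold) rose and LOH1 (at least 24.7-fold) and PP2-A6 (at least 8.77-fold) fell. At 15 days AP1 (at least 218-fold), AP3 (at least 210-fold), SEP2 (387-fold) and DELTA-VPE, a protease gene known from the seed coat (at least 91.4-fold), rose, and PP2-A8 (at least 38.5-fold) fell. The counts were 53 genes at 7 days and 59 at 15 days (limma), and 474 and 570 with slide as a term and 1 residual degree of freedom. Both counts were 0 without WT replicate 1 or 2 at 15 days. Without WT replicate 1 or 2 at 7 days they were 148 and 138 at 7 days, and 235 in either case at 15 days. No gene passed for a difference of the LFYasEMF1 effect between the ages (0 genes by limma, 374 at an unadjusted p under 0.05, 131 with slide as a term), so genes called at 1 age only are not shown to differ between ages.

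In the double mutant 8 genes passed at 7 days and 18 at 15 days. THI2.1, a thionin gene, rose at least 26.2-fold at 15 days, while CSA1 fell at least 43.3-fold and MRD1 76-fold. Chosen after their values were seen, AT5G17090 rose at least 440-fold at 7 days and 607-fold at 15 days, and AT4G04402 at least 172-fold and 264-fold, while AT4G07820 fell at least 224-fold and 332-fold and AT4G07825 at least 155-fold and 190-fold. The other AT4G07825 probe gave smaller changes, −3.98 and −4.23, so its probes disagree in size. AT4G07820 and AT4G07825 are among the 82 genes at background described below. By the probes chosen, none of these loci was particular to the double mutant. AT5G17090, AT4G04402, AT4G07820 and AT4G07825 stood at a log2 of 8.33, 10.11, −9.04 and −9.99 in LFYasEMF1 over both ages. The other AT4G07825 probe stood at −0.53 in LFYasEMF1. Neither count held without WT replicate 1 or 2 at 15 days, when both were 0. Without WT replicate 1 or 2 at 7 days they were 105 and 158 at 7 days and 154 in either case at 15 days, and with slide as a term they were 725 and 373. In ult1-3 no gene passed at 7 or 15 days (0 genes by limma, 286 and 294 at an unadjusted p under 0.05, 100 and 117 with slide as a term), with MRD1 at −5.10 and −5.81. Without WT replicate 1 or 2 at 7 days 17 genes passed at 15 days. Between the double mutant and LFYasEMF1 no gene passed at either age (0 genes by limma, 1718 and 1006 at an unadjusted p under 0.05, 491 and 300 with slide as a term, 79 and 72 without WT replicate 1 or 2 at 7 days). The polygalacturonase gene ADPG1 stood at 8.02 and the defence marker PR1 at 7.22 at 15 days (adjusted p = 0.199 and 0.533).

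WT seedlings of 15 and 7 days were compared to see what changes with age. Here too the spread between WT arrays of an age includes the slide difference, and with slide as a term all genes shared 1 variance. FT, the mobile signal of flowering, was at least 6.59-fold higher at 15 days (log2 4.06; 3.51 and 4.6 in the 2 same-numbered pairs of arrays), and SAG13, a marker of senescing leaves, was at least 25.2-fold higher (5.74). PAP20 was at least 12.4-fold lower and UMAMIT25 18.1-fold lower. None of these passed the limma test on 4 arrays (adjusted p = 0.62, 0.62, 0.6 and 0.6), nor did any gene (0 of 22355, 812 at an unadjusted p under 0.05), while 235 passed with slide as a term, 40 without WT replicate 2 at 7 days, and 1854 for the age term of the fit over all 10 arrays. With an estimated correlation no list passed here (adjusted p of 0.438 or more). With the preset correlation 10 lists passed. Lists that rose were glucosinolate synthesis (median 0.85, 13 of 13 higher, adjusted p = 3.13e-06), flowering time (0.47, adjusted p = 0.000134), cold, drought and abscisic acid (0.39, adjusted p = 0.00187), jasmonate and ethylene defence (0.26, adjusted p = 0.00258), the Polycomb and trithorax group (0.64, adjusted p = 0.00672) and salicylic acid defence (0.25, adjusted p = 0.00672). Lists that fell were the cell cycle (−0.75, adjusted p = 0.00187), root tissue (−0.68, adjusted p = 0.00344), the shoot meristem (−0.49, adjusted p = 0.00929) and auxin (−0.58, adjusted p = 0.0134). Without WT replicate 1 at 15 days the lists of flowering time, cold and drought, jasmonate and ethylene defence, root tissue, the shoot meristem and auxin did not pass (adjusted p = 0.0688, 0.362, 0.757, 0.101, 0.102 and 0.236), and salicylic acid defence turned downward (adjusted p = 0.978). Salicylic acid defence, the shoot meristem and auxin did not pass without WT replicate 2 at 7 days either (0.176, 0.289 and 0.122), the Polycomb and trithorax group not without WT replicate 1 at 7 days or 2 at 15 days (0.294 and 0.437), and root tissue not without WT replicate 1 at 7 days (0.294) or with slide, here the replicate, as a term (0.0593).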

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

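All patterns weighed below were picked because they stood out in the data, and the tests of a slide difference and of admixed wild type seedlings were chosen only after the floral result was seen, while for the other tests the predictions were written before the values they measure were seen. The first result singled out here is a difference between backgrounds. A test for an effect of LFYasEMF1 that differs between the ult1-3 and WT backgrounds passed at 31 genes (17 up, 14 down, limma, 1021 at an unadjusted p under 0.05), or 39 with slide as a term, of which 25 were among the 31. The count was 13 without either ult1-3 array or either double mutant array, 15 without LFYasEMF1 at 15 days, 19 without WT replicate 1 at 7 days and 55 without WT replicate 1 at 15 days, and 0 in the fit of the 8 group means. Its named genes were LOH1 (AT3G25440, fitted log2 6.88, adjusted p = 0.0228, and 0.0483 with slide as a term), MEO (−8.09, adjusted p = 0.0189, and 0.092 with slide as a term) and CSA1 (−6.27, adjusted p = 0.0057, and 0.0286 with slide as a term). The fitted values are not sizes of effects, since LOH1 lay at background in LFYasEMF1, CSA1 in the double mutant, and MEO in every genotype but LFYasEMF1. LOH1, whose other probe did not move the same way, and CSA1 are also among the 82 genes at background described below, so they do not show an effect that differs between backgrounds. Leaving out single arrays raised the adjusted p to as much as 0.159 for LOH1, 0.12 for MEO and 0.0572 for CSA1. The second result is a signal in data outside the gene counts. Of 5709 tested probes without a locus, 173 changed in LFYasEMF1 against WT (97 up, 76 down), and these were not analysed further.

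Clock transcripts differed between the WT arrays of slide 1 and those of the other slides. Evening minus morning genes, slide 1 minus the other slide, gave a median log2 of 8.90 at 7 days and 5.423 at 15 days, in genes other than the CCA1 and TOC1 pair that drew attention. An array or scan effect that acts on genes regardless of function is argued against, since 0% of 10000 matched random pairs of lists gave a value as large. Harvest at another time of day is a candidate explanation that the 5.423 is consistent with. Harvest times are not given, so whether slide 1 carries RNA from another day or hour stays open, as does how much of each genotype difference across slides follows from it.

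Floral organ identity genes lay between WT and LFYasEMF1 in the double mutant. A slide difference that shifts the list as a whole is argued against. The median changes against WT of the same slide were 4.69 in LFYasEMF1 and 1.17 in the double mutant at 7 days and 4.57 and 2.97 at 15 days. The smaller gap was 1.601, while the WT slides differed by medians of −0.05 and −0.12. Single dim genes differed more between WT slides 1 and 2 at 7 days, both ways, such as SEP1 (−9.71 and −6.35) and AP1 (−7.58 and −10.01). Each change sets 1 array against 1, and all LFYasEMF1 arrays lay on slide 1. An effect of the transgene that differs with the slide or its clock state is therefore not addressed. Wild type seedlings mixed into the double mutant samples are argued against too, since of 90 genes at least 4-fold below WT in LFYasEMF1 at both ages, 41 were also at least 4-fold below WT in the double mutant. A weaker activity of the transgene in the double mutant line stays open, since the EMF1 probe may read sense or antisense RNA. A smaller share of floral tissue or of affected seedlings was considered too and not tested, so it stays open.

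In LFYasEMF1 or the double mutant 82 genes measured on every WT array were called lower and lay at background at both ages. There were 66 in LFYasEMF1, 46 in the double mutant, 30 in both and 1 in ult1-3. Genes at background without a call are not counted, and only 3 genes were called lower in ult1-3, so these counts do not compare the lines. Among the 82 genes, 20 pairs lay within 5 genes of each other, such as PP2-A6, PP2-A7 and PP2-A8, against a median of 1 and a highest of 7 in 10000 random draws. That is consistent with stretches of chromosome that differ between the lines, such as parts from another accession, although neighbouring genes regulated together could give it as well. A sequence difference under the single probe cannot be told apart from lost expression, since 33.3% (4 of 12) of the cases with another probe had that probe within a log2 of 1 of WT. The parents of the lines are not described in enough detail to settle either point.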

How the results depend on the processing

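The repeats by normexp on median signals, by a block of slide 1 against slides 2 and 3, within slides and with probes without a locus, and no other tests here, were chosen only after the data were seen. Over 19 counts and restoration values, 296 repeats stayed near the value reported and 106 moved. Of repeats of the 28 lists that passed, 497 kept their call, 57 lost it and 6 turned direction, and of repeats for 146 named gene results 2603 stayed, 526 lost their call, 52 gained one and 7 turned direction. Direction thus held far more often than the call. Many of the named genes were picked for passing the test with the same direction at both ages, and the lists for passing. Their direction could hardly turn on largely the same arrays, so this does not show that directions are reliable. Except where fewer arrays enter, the cause of the lost and gained calls was not tested. The planned normexp on mean signals was not run as written. Signal over background limits the folds of dim genes, and those given as at least hold as lower bounds only. Some fitted folds, such as those of SEP2, SEP1, ARI3, TIF3C2 and DAR4, also rest in part on arrays at background. At a single age the lone mutant array was assumed to vary like the WT arrays.

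With the fit of 8 group means, over both ages, 155 genes changed in LFYasEMF1 against WT, 5 in ult1-3, 68 in the double mutant, 24 between the double mutant and LFYasEMF1, 24 between the double mutant and ult1-3, and 0 for the interaction. With slide as a block the counts over both ages moved to 8 for ult1-3, 327 for the double mutant and 67 for the double mutant against LFYasEMF1. At single ages, with 1 residual degree of freedom, they were 474 and 570 for LFYasEMF1, 100 and 117 for ult1-3, 725 and 373 for the double mutant, 491 and 300 for the double mutant against LFYasEMF1, 131 for genotype by age and 235 for age in WT, and the restoration differences were −2.92 and −2.62. For WT age the slide term is the replicate block, with 235 genes by that replicate block, and the age term of all 10 arrays gave 1854. In the fits at single ages and of WT age, the slide term left all genes with 1 common variance. Those counts can therefore not be read as a gain from the term. Within slides 2 and 3 ult1-3 had 5 genes, and with the block of slide 1 against slides 2 and 3 the double mutant and LFYasEMF1 differed at 63.

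With a filter of 5 arrays ult1-3 had 7 genes and the double mutant at 7 days 22, and restoration was −2.02 and −1.93. With a floor under dim signals ult1-3 had 8, LFYasEMF1 at 7 days 33 and the double mutant at 7 days 13. With no filter the double mutant at 7 days had 27. With probes without a locus the interaction had 56, LFYasEMF1 at 7 days 87 and the double mutant at 7 days 16. Normexp on median signals gave 0 and 0 for LFYasEMF1 and 0 and 0 for the double mutant at 7 and 15 days, and restoration of −1.63 and −1.47. The authors' value table gave 29 and 10 for the double mutant at 7 and 15 days, and quantile normalization 11 at 15 days. The mean of probes gave 22 for the double mutant at 7 days and −2.75 for restoration at 15 days. An intensity trend with robust variances gave 26 and 28 for the double mutant, and 7 and 6 for the double mutant against LFYasEMF1, at 7 and 15 days. Restoration was −4.47 and −3.78 for 50 genes and −1.61 and −1.21 for 500, and −2.06 at 15 days with LFYasEMF1 set against WT replicate 1 and the double mutant against WT replicate 2.

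Leaving out each array in turn gave, lowest to highest, 181 to 563 for LFYasEMF1 against WT, 5 to 17 for ult1-3, 120 to 230 for the double mutant, 45 to 293 for the double mutant against LFYasEMF1, 23 to 78 for the double mutant against ult1-3 and 13 to 55 for the interaction. At 7 and 15 days it gave 0 to 148 and 0 to 235 for LFYasEMF1, 0 to 0 and 0 to 17 for ult1-3, 0 to 158 and 0 to 154 for the double mutant, and 0 to 79 and 0 to 72 for the double mutant against LFYasEMF1. Genotype by age stayed at 0, WT age ran from 0 to 40, restoration from −2.81 to −2.28 and from −2.57 to −2.24, and the number of lists that passed from 25 to 40. Here fewer arrays enter each fit.

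Lists that gained a call in other repeats, such as by leaving out an array, are not named here. Some lists that did not pass in the fit reported above passed with slide as a block. These were the circadian clock in the double mutant against WT, LFYasEMF1 and ult1-3 (adjusted p = 0.00804, 0.00787 and 0.00344), the Polycomb and trithorax group in ult1-3 and in the double mutant against LFYasEMF1 and ult1-3 (0.00139, 0.00274 and 0.0482), photosynthesis in ult1-3 and in the double mutant against LFYasEMF1 (0.000498 and 0.029), flowering time in the double mutant (0.024), glucosinolate synthesis in the double mutant against LFYasEMF1 (0.029), cold, drought and abscisic acid in the double mutant against ult1-3 (0.0175), heat shock in ult1-3, the double mutant against WT and ult1-3, and WT age (0.0375, 0.00804, 0.0482 and 0.00281), and leaf senescence in WT age (0.00182). None of them passed with slide as a block and an estimated correlation (adjusted p from 0.488 to 0.984). The cause was not tested.

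Of the results that turned direction, the photosynthesis list in the double mutant had an adjusted p of 0.677 with quantile normalization, 0.63 with normexp on median signals and 0.639 with the authors' value table. The heat shock list between the double mutant and LFYasEMF1 had 0.2 with slide as a block and 0.208 with the block of slide 1 against slides 2 and 3, and salicylic acid defence in WT had 0.978 without WT replicate 1 at 15 days (lowest 7.4e-07, without WT replicate 2 at 15 days). ULT1 in LFYasEMF1 against WT, at −0.04, had 0.03 (0.027) with normexp on median signals, 0.27 (0.269) with slide as a block, with the block of slide 1 against slides 2 and 3 and within slide 1, 0.07 (0.069) without WT replicate 2 at 7 days, 0.09 without WT replicate 2 at 15 days and 0.33 (0.332) without LFYasEMF1 at 15 days, the highest, against a lowest of −0.41 (−0.409) without LFYasEMF1 at 7 days.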

Other observations

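The tests of gene lists in this part were fixed in advance, while the tests against WT of the same slides, those of probes without a locus and the comparison of ULT1 with other genes lowered in ult1-3 were chosen only after the data were seen. The double mutant against WT showed 3 further lists past the threshold over both ages. Seed maturation genes rose as a list (median 1.07, or 0.91 with dim genes at their bound, and 0.52 against WT of the same slides; adjusted p = 0.0394, and adjusted p = 0.712 with an estimated correlation). The median was 2.09 at 7 days and 0.14 at 15 days, and the called member SESA5, a seed storage albumin gene, rose at least 1.92-fold (adjusted p = 0.0427 by limma, and 0.0719 with slide as a term). Photosynthesis genes were slightly higher (median 0.19, 22 of 25 higher, adjusted p = 0.0394, and adjusted p = 0.839 with an estimated correlation), but the list turned downward with quantile normalization, normexp on median signals and the authors' value table (adjusted p = 0.677, 0.63 and 0.639). The Polycomb and trithorax list fell (median −0.34, adjusted p = 0.0394, and adjusted p = 0.839 with an estimated correlation), and its called member was ULT1, the gene that the mutant allele alters. None of the 3 lists passed without the double mutant array at 7 days (adjusted p = 0.714, 0.647 and 0.257).

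Among small heat shock protein genes, HSP17.6II, HSP17.6A and HSP17.4 moved with the slides, while HSP18.2 moved with the genotypes. HSP17.6II stood at −7.42 and −7.10 in WT and −7.04 and −6.75 in LFYasEMF1 on slide 1, and at 0.42 and −1.99 in WT, −0.85 and −1.83 in ult1-3 and −1.60 and −2.97 in the double mutant on slides 2 and 3. The median of the heat shock list was 1.19 in ult1-3 and 1.40 in the double mutant against all WT arrays. Against WT of the same slides it was −0.61 and −0.74, with 0 and 1 of 10 genes higher. HSP18.2 stood between −4.90 and −3.67 on the WT and ult1-3 arrays of all slides and between −7.02 and −6.38 on the LFYasEMF1 and double mutant arrays. It fell by 2.95 ± 0.31 in LFYasEMF1 and by 2.56 ± 0.31 in the double mutant against WT (adjusted p = 0.00271 and 0.00943 by limma). The first call was lost without LFYasEMF1 at 15 days (adjusted p = 0.0529) and the second without the double mutant at 7 or 15 days (adjusted p = 0.106 and 0.058).

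ULT1 was less reduced in ult1-3 (−2.06 ± 0.35, 4.17-fold) than in the double mutant (−5.65 ± 0.35). Where the ULT1 probes lie relative to the lesion is not given, so neither value tells how much functional transcript is lost. MRD1 fell 43.8-fold in ult1-3 (−5.45 ± 0.26), a call kept with slide as a term and without any 1 array. A share of seedlings of the WT line large enough to hold ULT1 at 4.17-fold below WT would have held MRD1 near that level too. That argues against seedlings of the WT line among ult1-3 as the whole reason for the difference. It cannot address seedlings that carry an intact ULT1 and low MRD1. MRD1 was also picked for its large decrease on these same arrays.

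Probes without a locus changed in the other comparisons as well, 5 in ult1-3 and 75 in the double mutant against WT, 93 between the double mutant and LFYasEMF1 and 42 between the double mutant and ult1-3.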
